A study of Homo sapiens with 16 samples.

How the data were processed

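RNA of U2OS cells, an established human osteosarcoma line, was profiled by sequencing after 6 h of treatment. Per the labels' protocols, cells in culture dishes received CPT, T4 or T5, total RNA was taken with a column kit, and libraries made by the sequencer manufacturer's procedure were read on a HiSeq instrument. The 16 libraries were 1 with DMSO, the solvent control, and 5 for each of 3 compounds, at 0.5, 2, 5, 10 and 20 µM. The labels call the samples total RNA in one field and mRNA in another, and do not say how polyadenylated RNA was selected or whether libraries kept the strand, so genes that overlap on opposite strands cannot be told apart here.

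The values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), deposited by the authors as a single matrix with 1 column per library, per the file headers. GSNAP, Cufflinks and the builds hg19 and GRCh37 are named in the submitters' processing notes, with no roles; tool versions, the annotation and any filters are not given in the sources used here. The matrix held 25270 genes once 2 inner header lines, 1 incomplete line and 220 repeats of earlier lines, all with identical values, had been left out. Of these genes, 4531 were listed at 0 in every library. FPKM summed to between 238669 and 285143 per library. An exact 0 in such a file can be a failed estimate, and no gene encoded by mitochondrial DNA was measured.

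Total depth is unknown, because FPKM divides it out. Low values still come in steps of what 1 fragment is worth, and comparing these steps below an FPKM of 0.2, on a grid smoothed with a width of 0.02 log2 units, gave the depth of each library relative to DMSO. It ranged from 0.637 for 5 µM T5 to 0.993 for 0.5 µM T5, and that of 0.5 µM T5 cannot be told from DMSO on this grid, while the other treated libraries were shallower. Whole fragments were not recovered for all genes, so no count test was run and no counting interval is given.

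From the deposited values, log2(FPKM + 1) was computed for the 10600 genes with a mean FPKM of at least 1 over all 16 libraries. A fold change on this scale understates the change of genes with low FPKM. Tests used limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8), moderated variances with a mean-variance trend, 2-sided p-values and Benjamini-Hochberg adjustment at 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. For each compound, log2(FPKM + 1) of its 5 libraries and the DMSO library was fitted on log2(1 + dose / 0.5 µM), and the slope was scaled to the fitted change from 0 to 20 µM. For each pair of compounds, the mean difference over the 5 shared doses was tested with dose as a block, without the DMSO library. The difference of dose slopes was tested on DMSO and the 10 libraries of both compounds with a common intercept, so a difference in level already present at the lowest dose counts as slope. It was tested again with an intercept for each compound on the treated libraries, an alternative added after the results were seen. Similarity of trends was measured across genes on slopes fitted to treated libraries alone, so that no library was shared. For a single dose against DMSO there was 1 library on each side, so only ratios are given. Each dose has 1 library and nothing says that the libraries came from separate cultures, so p-values measure the scatter of single libraries around a line or around a mean difference, which may be technical and includes curvature.

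The tests, the processing alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each dose trend, the 8 rising and 8 falling genes with the largest fitted change among those past the threshold with the same sign of ratio to DMSO at all 5 doses. For each comparison at matched doses it took the 5 higher and 5 lower genes with the largest mean difference on the same terms. It added up to 4 members of each list with the largest absolute change, called or not, all cleavage and polyadenylation factors, and MDM2, CDKN1A and TOP1, and passed over pseudogenes and genes without a symbol. Lists covered cleavage and polyadenylation factors, the Integrator complex, nuclear RNA decay factors, SR proteins and CLK kinases, the positive elongation factor and its regulators, and DNA topoisomerases. They also covered targets of p53, NF-kB, NRF2 and the aryl hydrocarbon receptor, and genes of the immediate early, integrated stress, unfolded protein, heat shock, hypoxia and interferon responses. Cholesterol synthesis, G1/S and replication, G2/M, Fanconi anaemia and homologous recombination, replication-dependent histone, cytosolic ribosomal protein, mitochondrially encoded, and bone and osteoblast genes followed, with markers of epithelial and blood cells that should be scarce in this line.

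Lists with at least 5 measured members were tested with camera, which asks whether a list's genes changed more in one direction than other genes did, with a preset correlation of 0.01 between genes and again with an estimated one. None of the list calls at the preset correlation held with an estimated correlation. Because camera places a list relative to other genes, whose own median was not at 0, its sign differed from that of the list's median or mean for hypoxia and cholesterol synthesis genes in several trends, for unfolded protein response, heat shock, NRF2 target, interferon and bone genes with T4 and T5, and for integrated stress response genes with T5. The same held in the matched comparisons for cholesterol synthesis genes in all of them, for p53 target, histone and interferon genes between T4 and T5, for cleavage factors, SR proteins and topoisomerases between T4 or T5 and CPT, and for Integrator, RNA decay and elongation genes between T5 and CPT. At single doses, a list's median ratio to DMSO was ranked among 10000 random lists of the same size matched on mean expression, as a description of those libraries.

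The fitting code was tested on simulated data with 10600 genes, 100 of them changed by 1 and 100 by 2 on the log2 scale. For the dose trends it recovered 34% (CPT), 39% (T4) and 34% (T5) of the smaller changes and 92%, 91% and 89% of the larger ones. For matched doses it recovered 97% of the smaller changes between T4 and T5, 97% between T4 and CPT and 93% between T5 and CPT, and 99%, 100% and 99% of the larger ones. For slope differences the shares were 76%, 62% and 56%, and 97%, 96% and 94%. False calls numbered 4 to 12 among 10400 unchanged genes. The simulated noise was independent between genes and libraries, around an exact line or block mean. It held no shift of whole libraries and no curvature, so these figures are not error rates of the real calls.

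Alternatives covered the pseudocount, the filter on low values, median centring, quantile normalization, the dose scale, the DMSO library, pooled fits, the variance trend, a minimum change, the dose block and leaving out each library or dose in turn. Added after the data were seen were a run without small RNAs, with library totals equalised, and a run of the T5 trend without 5 and 20 µM. Gene symbols were compared with GENCODE release 29, where 22597 matched directly, 900 matched an older symbol and 1773 did not match. That annotation is on GRCh38, not on the build in the processing notes, and the file gives no positions, so no coordinates are printed and the annotation was used only for gene types and gene spans.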

Results

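Gene expression was measured in U2OS cells 6 h after adding CPT, T4 or T5, the latter a pair of compounds that the series describes as modulators of alternative polyadenylation, the choice between sites at which the 3' end of an mRNA is cut and given its poly(A) tail. Each compound was given at 0.5, 2, 5, 10 and 20 µM, with 1 library per dose and 1 DMSO library, so no condition has a replicate and tests rest on trends over doses or on differences over matched doses. Total depth is unknown, but relative depth read from the steps of low values lay between 0.637 and 0.993 of that of the DMSO library. Errors after ± are standard errors of the fit, over 6 libraries for a dose trend and 10 for a comparison at matched doses, and changes are on the log2(FPKM + 1) scale.

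The number of genes lower than in DMSO by at least 2-fold on that scale grew with each dose of T4 and T5, and with CPT up to 10 µM (2258). The number of higher genes did not, with a peak of 239 at 2 µM T4 and of 349 at 10 µM T5, and between 576 and 649 from 2 to 20 µM CPT. With CPT the counts were 260 higher and 722 lower at 0.5 µM and 649 higher and 2228 lower at 20 µM. At 0.5 µM, 39 genes were higher and 109 lower with T4, and 128 were higher and 467 lower with T5. At 20 µM these counts were 127 and 2430 with T4 and 259 and 2806 with T5. These single-library ratios have no replicate check.

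**Figure D1:**
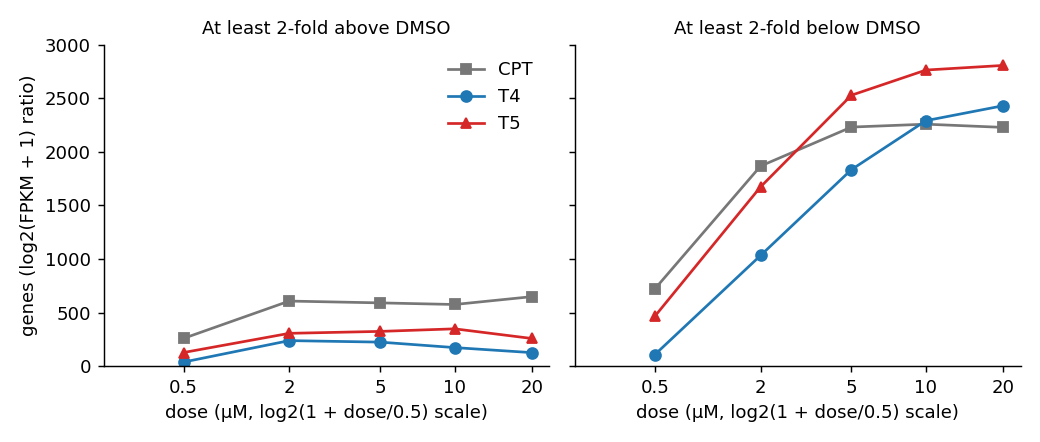
Number of genes at least 2-fold higher or lower than in DMSO (on the log2(FPKM + 1) scale) in each treated library, by dose in µM, with 1 library per point. At 0.5 µM the count of lower genes was 722 with CPT, 109 with T4 and 467 with T5, and at 20 µM it was 2228, 2430 and 2806.

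CPT trend with dose. FOS and JUNB, immediate early transcription factors that are induced within minutes of a stimulus, rose by 3.96 ± 0.45 and 4.17 ± 0.46 between 0 and 20 µM CPT, and the chemokine CXCL8 rose by 4.32 ± 0.98. AURKA, a kinase needed for mitosis, fell by 2.89 ± 0.37, from an FPKM of 40.6 in DMSO to 4.41 at 20 µM. FIP1L1, a subunit of the complex that recognises the polyadenylation signal, fell by 2.79 ± 0.31. TOP1, the enzyme that relaxes supercoiled DNA by cutting a single strand, fell by 1.13 ± 0.34 (adjusted p = 0.0384, limma).

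Across all genes, 1899 rose and 2739 fell with CPT dose (limma, Benjamini-Hochberg). The largest rises under the naming rule also included ANKRD30BL (5.67 ± 0.43), the long noncoding RNA LINC00273 (5.31 ± 0.24), the polyamine-acetylating enzyme SAT1 (4.34 ± 0.98), the chemokine CXCL3 (3.84 ± 0.48) and SHISA2 (3.78 ± 0.74). The falls included the SUMO ligase PIAS1 (-3.39 ± 0.58), FRMD6 (-3.37 ± 0.66), the spindle motor KIF11 (-3.33 ± 0.71), the elongation factor partner IWS1 (-3.26 ± 0.58) and GPBP1 (-3.25 ± 0.43). With them fell the sialyltransferase ST3GAL1 (-3.25 ± 0.54) and CDK7, the kinase of transcription factor IIH (-3.24 ± 0.39). Adjusted p of these genes by limma lay between 0.0033 for LINC00273 and 0.0176 for SAT1.

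Among 20 cleavage and polyadenylation factors, 9 fell, 2 rose and 9 were not called with CPT, with the same counts adjusted over the list alone. WDR33, which binds the polyadenylation signal, fell by 2.40 ± 0.45, the poly(A) polymerase PAPOLG by 1.91 ± 0.31 and the cleavage stimulation factor CSTF1 by 1.64 ± 0.33. CSTF3, CPSF4, CPSF3, CPSF7 and CSTF2 fell by 1.33, 1.29, 1.21, 0.94 and 0.62. CLP1, a subunit of cleavage factor II, rose by 1.64 ± 0.52 (adjusted p = 0.0448, limma), from an FPKM of 7.40 in DMSO to 30.8 at 20 µM, and CPSF1 rose by 0.92 ± 0.19. Values for CSTF2T and PCF11 were -0.60 ± 0.32 and -0.56 ± 0.43, and neither passed the test, nor did NUDT21 (-0.02 ± 0.15), CPSF6 (-0.21 ± 0.15), PAPOLA (-0.04 ± 0.24), RBBP6 (0.06 ± 0.23), SYMPK (0.29 ± 0.12), PABPN1 (0.70 ± 0.26) or CPSF2 (-1.12 ± 0.49). The list's camera adjusted p was 0.165, and 0.613 with an estimated correlation.

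Of 16 immediate early genes, 12 rose and none fell with CPT, and adjusted over the list alone 15 rose. Their median change was 1.84 and camera gave an adjusted p of 2.99e-08, but adjusted p = 0.613 with an estimated correlation. FOSB rose by 3.63 ± 0.29 and EGR1 by 2.37 ± 0.34. Of 20 G2/M genes, 14 fell and 1, BIRC5, rose, with 15 falling and 1 rising adjusted over the list alone. The spindle checkpoint kinase BUB1B fell by 2.67 ± 0.76 and the kinetochore proteins CENPF and CENPE by 2.44 ± 0.43 and 2.26 ± 0.61. Camera gave this list an adjusted p of 0.00328, and adjusted p = 0.613 with an estimated correlation.

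Of 15 nuclear RNA decay factors, 8 fell and 1 rose with CPT, with 9 falling and 1 rising adjusted over the list alone, among them the exosome subunits EXOSC3 (-2.35 ± 0.38) and EXOSC9 (-2.18 ± 0.27) and the exosome adaptor RBM7 (-2.28 ± 0.32). Of 15 Fanconi anaemia and homologous recombination genes, 7 fell and none rose, also when adjusted over the list alone, with the helicase BLM at -2.60 ± 0.49. Both lists had a camera adjusted p of 0.0268, and adjusted p = 0.613 and 0.668 with an estimated correlation. The elongation kinases CDK13 (-2.77 ± 0.53) and CDK12 (-2.34 ± 0.47) were among 8 of 15 genes of the elongation list that fell, while CDK9 rose. Adjusted over the list alone, 8 fell and 2 rose. Of 60 cytosolic ribosomal protein genes, 53 rose and none fell as deposited, with RPS2 at 0.99 ± 0.15 and RPL13 at 0.92 ± 0.13, but with quantile normalization 4 rose and 5 fell and the median moved from 0.64 to 0.03. Adjusted over the list alone 56 rose, and camera gave an adjusted p of 5.96e-16, but adjusted p = 0.613 with an estimated correlation. RPL21 was near 0 in 8 of 16 libraries, including DMSO, and is uncertain.

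The p53 target genes were already higher at the lowest CPT dose. Their median log2 ratio to DMSO was 1.37 at 0.5 µM and 0.56 at 20 µM. The cell cycle inhibitor CDKN1A had an FPKM of 31.6 in DMSO, 127.5 at 0.5 µM and 137.4 at 20 µM. The antiproliferative gene BTG2 went from 4.45 in DMSO to 41.8 at 0.5 µM and 52.7 at 20 µM, and MDM2, the ubiquitin ligase of p53, from 13.2 to 34.1 and then 6.30. A straight trend over dose called 3 of 26 members rising (GADD45A, TP53I3 and PMAIP1) and 1 falling (POLH), and 0 of either adjusted over the list alone. Trend values were 1.54 ± 0.65 for CDKN1A, 2.56 ± 1.02 for BTG2 and -1.84 ± 0.62 for MDM2, none of them called.

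Without the 10 µM library the CPT trend called 1 gene rising and 0 falling, without 0.5 µM 1005 and 1535, without 5 µM 1121 rising, and on a linear dose scale none. Median centring gave 3572 rising and 1643 falling, and quantile normalization 2341 and 1910.

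**Figure D2:**
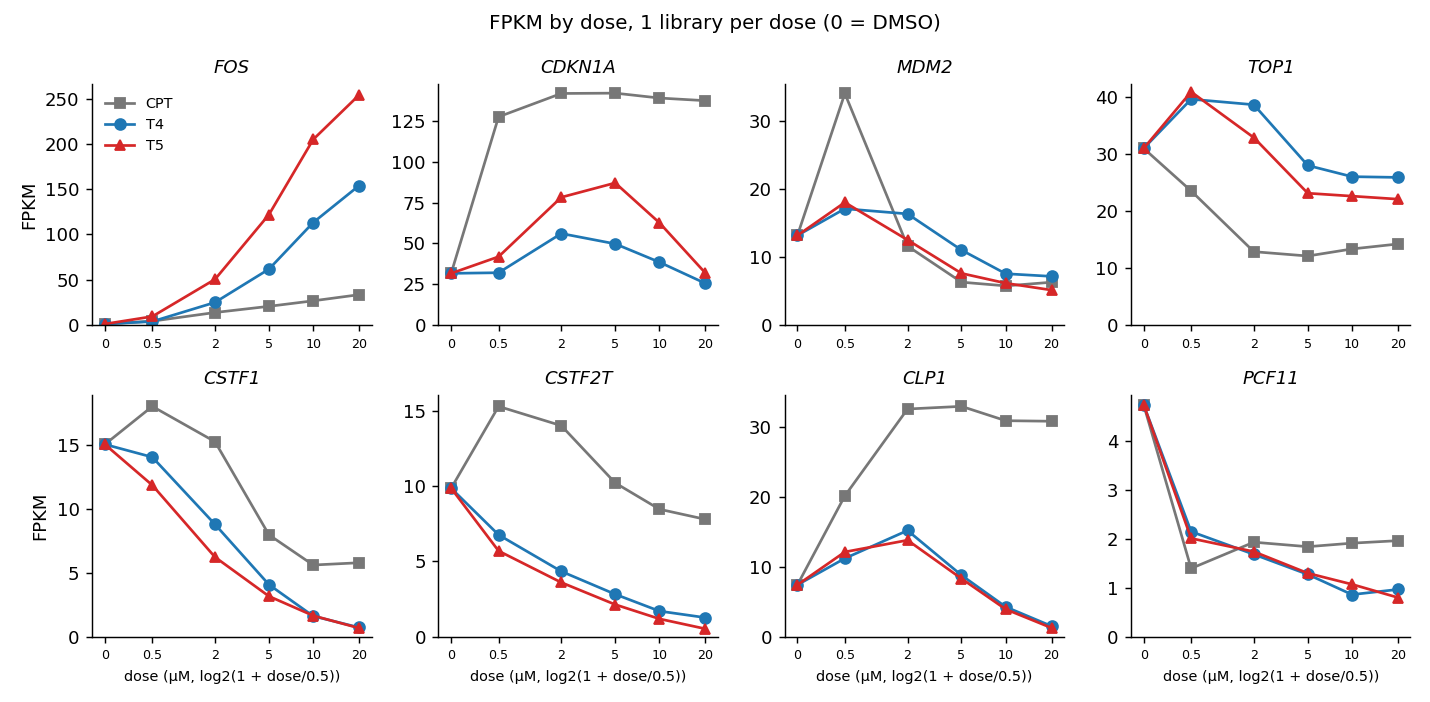
FPKM of FOS, CDKN1A, MDM2, TOP1, CSTF1, CSTF2T, CLP1 and PCF11 against dose in µM for CPT, T4 and T5, with 1 library per point and DMSO at dose 0. CLP1 reached 30.8 with 20 µM CPT but 1.51 with T4 and 1.25 with T5, and CDKN1A was 127.5 with 0.5 µM CPT against 32.0 with T4 and 41.8 with T5.

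T4 trend with dose. The strongest rise was that of FOS, at 6.51 ± 0.46, from an FPKM of 1.13 in DMSO to 153.8 at 20 µM T4. CXCL8 rose by 5.68 ± 0.41, the transcription factors EGR1 and JUNB by 5.02 ± 0.39 and 5.01 ± 0.30, and the chemokine CCL2 by 3.82 ± 0.37. CSTF1, a subunit of the cleavage stimulation factor that binds the RNA downstream of the poly(A) site, fell by 3.45 ± 0.34, from an FPKM of 15.1 to 0.718. TNFRSF1A, a receptor of tumour necrosis factor, fell by 4.22 ± 0.23, and AURKA fell by 4.15 ± 0.57.

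In all, 1533 genes rose and 3438 fell with T4 dose (limma, Benjamini-Hochberg). ARC (4.89 ± 0.55), ANKRD30BL (3.93 ± 1.08) and LINC00273 (3.84 ± 0.71) completed the named rises. Further named falls were TMEM60 (-3.92 ± 0.33), the mitochondrial import chaperone TIMM9 (-3.77 ± 0.30), ZBED5 (-3.73 ± 0.28), TTC4 (-3.57 ± 0.29), TBPL1, a relative of the TATA-binding protein (-3.56 ± 0.22), and the Golgi protein GOLPH3 (-3.50 ± 0.29). KRTAP20-4 also passed (-3.93 ± 0.71), but it was listed at 0 from 5 µM upwards and at 5.35 and 6.18 below, against 9.50 in DMSO. Adjusted p of these 16 genes by limma lay between 0.00121 for FOS and 0.0241 for ANKRD30BL.

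Of the 20 cleavage and polyadenylation factors, 9 fell, 2 rose and 9 were not called with T4, again with the same counts adjusted over the list alone. With median centring, 7 fell and 6 rose. After CSTF1 came WDR33 (-2.38 ± 0.39), CSTF2T, a paralog of CSTF2 (-2.30 ± 0.18), PAPOLG (-2.15 ± 0.30), FIP1L1 (-1.76 ± 0.39), CPSF4 (-1.51 ± 0.19), PCF11, a subunit of cleavage factor II (-1.45 ± 0.27), CPSF7 (-1.15 ± 0.14) and CSTF2 (-0.58 ± 0.13). CPSF1 rose by 0.54 ± 0.11 and NUDT21 by 0.46 ± 0.12. CLP1 had FPKM values of 7.40 in DMSO, 15.2 at 2 µM and 1.51 at 20 µM, and its trend of -1.76 ± 0.72 was not called (adjusted p = 0.0857, limma). CSTF3, RBBP6, CPSF3, CPSF2, PABPN1, PAPOLA, SYMPK and CPSF6 were not called either, with values between -1.03 ± 0.40 for CSTF3 and 0.32 ± 0.14 for PABPN1. Camera gave the list an adjusted p of 0.323, and 0.653 with an estimated correlation.

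Of the immediate early genes, 14 of 16 rose with T4, also when adjusted over the list alone, and 1, FOSL1, fell. The median was 1.83 and the camera adjusted p 1.0001e-09, but adjusted p = 0.468 with an estimated correlation. IER2 rose by 3.38 ± 0.12. Of 13 NF-kB target genes, 5 rose, with CCL20 at 3.48 ± 0.54 and CXCL3 at 2.96 ± 0.36, while 4 fell (NFKBIE, BIRC3, RELB and NFKB2), with the same counts adjusted over the list alone. The list was not called by camera (adjusted p = 0.214).

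Falling groups with T4 included 14 of 20 G2/M genes, with cyclin A2 (CCNA2) at -2.55 ± 0.23, KIF23 at -2.34 ± 0.52 and BUB1B at -2.14 ± 0.25, and none rising. The camera adjusted p was 0.00379, but adjusted p = 0.468 with an estimated correlation. Of 15 nuclear RNA decay factors, 10 fell and 1 rose, with RBM7 at -2.87 ± 0.43 and ZCCHC8, another exosome adaptor subunit, at -1.99 ± 0.19. Camera gave an adjusted p of 0.0438, but adjusted p = 0.468 with an estimated correlation. Counts for both lists were the same adjusted over the list alone. MEPCE, which caps the 7SK RNA that holds the positive elongation factor inactive, fell by 3.14 ± 0.34, and the splicing factor SRSF4 and its kinase CLK2 fell by 2.79 ± 0.25 and 1.67 ± 0.20. In the elongation list 6 of 15 fell, among SR proteins and CLK kinases 7 of 16 fell and 1 rose, and in the Integrator complex, which ends transcription of small nuclear RNAs, 4 of 14 fell (INTS5 at -2.35 ± 0.17) and 1 rose. These 3 lists had the same counts adjusted over the list alone, and none was called by camera. Of all 10600 genes 3438 fell with T4, so the Integrator count is no sign of a fall of that complex beyond other genes. With median centring the medians of the SR protein and Integrator lists turned positive.

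The p53 target genes showed 3 rising and 10 falling of 26 with T4, also when adjusted over the list alone, and median centring turned the split to 11 rising and 5 falling. Camera did not call this list (adjusted p = 0.977, and 0.985 with an estimated correlation). Of all 10600 genes, 1533 rose and 3438 fell. PPM1D, the phosphatase that acts against p53, fell by 2.27 ± 0.50, AEN fell by 1.998 ± 0.19, SESN2 by 1.89 ± 0.50 and MDM2 by 1.08 ± 0.31, while the apoptosis inducer BBC3 rose by 1.54 ± 0.49. CDKN1A had FPKM values of 56.0 at 2 µM and 25.5 at 20 µM, and its trend was -0.07 ± 0.43. TOP1 was at -0.49 ± 0.22 and was not called. Of 60 ribosomal protein genes 54 rose as deposited, with RPS9 at 0.81 ± 0.14, RPLP1 at 0.79 ± 0.14 and RPLP0 at 0.79 ± 0.14, but with quantile normalization 16 rose and 6 fell and the median moved from 0.58 to 0.09. Adjusted over the list alone 55 rose, and the camera adjusted p was 2.1e-20, but adjusted p = 0.653 with an estimated correlation.

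Without the 0.5 µM library 785 genes rose with T4, without 10 µM 850 rose, and on a linear dose scale 99 rose and 1328 fell. Median centring gave 4293 rising and 1847 falling, and quantile normalization 2806 and 2101.

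T5 trend with dose. FOS rose by 6.92 ± 0.71, to an FPKM of 253.8 at 20 µM, CXCL8 by 6.04 ± 0.37, EGR1 by 5.39 ± 0.58 and JUNB by 5.27 ± 0.41. AURKA fell by 5.10 ± 0.44, from an FPKM of 40.6 to 0.549, and CCNA2 and the mitotic kinase PLK1 fell by 3.16 ± 0.15 and 3.11 ± 0.39. CSTF1 fell by 3.36 ± 0.21 and CSTF2T by 2.75 ± 0.17, and SRSF4 by 3.45 ± 0.21.

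With T5, 1929 genes rose and 3658 fell (limma, Benjamini-Hochberg). Other named rises were ANKRD30BL (5.33 ± 1.10), ARC (5.23 ± 0.79), CCL20 (4.45 ± 0.39) and SAT1 (4.36 ± 0.95). Named falls were FRMD6 (-4.21 ± 0.53), CDCA8, a subunit of the chromosomal passenger complex (-3.97 ± 0.21), TMEM60 (-3.96 ± 0.38), the spindle protein FAM83D (-3.93 ± 0.25), TNFRSF1A (-3.86 ± 0.40), GOLPH3 (-3.78 ± 0.41) and ZBED5 (-3.67 ± 0.38). The small nucleolar RNA SNORA84 also passed, but its values were 153.1 in DMSO, 143.0 at 0.5 µM and listed at 0 from 2 µM upwards, and FPKM of so short a RNA is unreliable. Adjusted p of these 16 genes by limma lay between 0.000865 for CXCL8 and 0.014 for SNORA84.

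Of the 20 cleavage and polyadenylation factors, 9 fell, 2 rose and 9 were not called with T5, with the same counts adjusted over the list alone, and with median centring 8 fell and 5 rose. The falls were CSTF1, CSTF2T, WDR33 (-2.35 ± 0.47), PAPOLG (-2.18 ± 0.26), FIP1L1 (-1.70 ± 0.29), CPSF7 (-1.65 ± 0.12), CPSF4 (-1.57 ± 0.27), PCF11 (-1.44 ± 0.27) and CSTF2 (-0.63 ± 0.12). CPSF1 rose by 0.72 ± 0.08 and PABPN1 by 0.68 ± 0.14. The trend of CLP1 was -1.96 ± 0.73 (adjusted p = 0.0622, limma), with FPKM values of 13.8 at 2 µM and 1.25 at 20 µM. The remaining members lay between -1.08 ± 0.49 for RBBP6 and 0.44 ± 0.22 for SYMPK and were not called. The list's camera adjusted p was 0.238, and 0.722 with an estimated correlation.

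Of 16 immediate early genes, 14 rose and 1, FOSL1, fell with T5, also when adjusted over the list alone, with a median of 2.26. The camera adjusted p was 6.73e-08, but adjusted p = 0.722 with an estimated correlation. Of 20 G2/M genes, 16 fell and none rose, also when adjusted over the list alone, and camera gave an adjusted p of 0.000431, but adjusted p = 0.548 with an estimated correlation. Of 60 ribosomal protein genes, 52 rose and 1 fell as deposited, with RPS2 at 1.06 ± 0.18, but with quantile normalization 10 rose and 11 fell. Adjusted over the list alone 56 rose and 1 fell, and camera gave an adjusted p of 1.67e-14, but adjusted p = 0.798 with an estimated correlation.

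Of 26 p53 target genes, 3 rose (GDF15, GADD45A and FDXR) and 10 fell with T5, and adjusted over the list alone 4 rose and 10 fell, but with median centring 10 rose and 8 fell. Camera did not call this list (adjusted p = 0.875, and 0.910 with an estimated correlation). Of all 10600 genes, 1929 rose and 3658 fell. PPM1D fell by 2.61 ± 0.40, SESN2 by 2.04 ± 0.43, XPC, a DNA damage sensor, by 1.81 ± 0.32, and MDM2 by 1.54 ± 0.29. CDKN1A had FPKM values of 87.0 at 5 µM and 31.9 at 20 µM, with a trend of 0.35 ± 0.65. TOP1 fell by 0.76 ± 0.23. Among RNA-processing groups, 11 of 15 nuclear RNA decay factors fell and 1 rose (RBM7 at -2.97 ± 0.32), 8 of 16 SR proteins and CLK kinases fell (SRSF3 at -2.40 ± 0.38), 8 of 15 genes of the elongation list fell (MEPCE at -2.67 ± 0.18), and 6 of 14 Integrator genes fell and 2 rose (INTS12 at -2.30 ± 0.28), although the Integrator median turned positive with median centring. These 4 lists had the same counts adjusted over the list alone, and camera called none of them.

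Without the 10 µM library 1152 genes rose with T5, and without both 5 and 20 µM, whose 10 most abundant genes took 10.0% and 10.1% of the FPKM, 823 rose and 2137 fell. Median centring gave 4388 rising and 1992 falling, quantile normalization 3013 and 2344, and a linear dose scale 23 and 545.

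**Figure D3:**
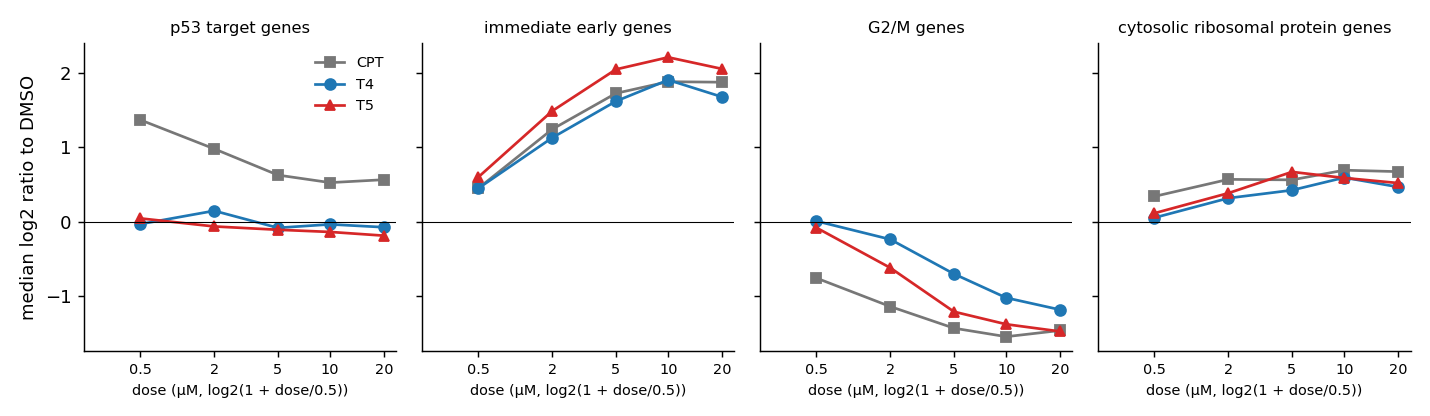
Median log2 ratio to DMSO of p53 target, immediate early, G2/M and ribosomal protein genes at each dose in µM, with 1 library per point. With CPT the p53 target median was 1.37 at 0.5 µM and 0.56 at 20 µM, while G2/M medians at 20 µM were -1.47 (CPT), -1.19 (T4) and -1.48 (T5); the rise of the ribosomal protein trend median was lost or reversed with quantile normalization.

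Median centring moved the median fitted change of all genes from -0.14 to 0.31 (CPT), from -0.27 to 0.38 (T4) and from -0.29 to 0.38 (T5), and quantile normalization moved it to 0.07, 0.08 and 0.07. Relative to the median of all genes, which centring leaves as it was, cleavage and polyadenylation factors lay at -0.47 (CPT), -0.75 (T4) and -0.69 (T5), G2/M genes at -1.14, -0.96 and -1.14, and immediate early genes at 1.97, 2.10 and 2.56. With quantile normalization these lists kept their sides, at -0.48, -0.75 and -0.69 for the factors, -1.21, -1.15 and -1.53 for G2/M genes, and 1.80, 1.88 and 2.65 for immediate early genes.

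Overlap of the trends. T4 and T5 shared 1442 rising and 3157 falling genes, and 0 genes were called in opposite directions. T4 and CPT shared 1146 rising and 2045 falling genes and had 92 that fell with T4 and rose with CPT and 1 that did the reverse. T5 and CPT shared 1384 and 2174, with 75 and 1 opposite. All 3 compounds shared 1115 rising genes, such as FOS, CXCL8, JUNB, EGR1 and ANKRD30BL, and 1952 falling genes, such as AURKA, CSTF1, WDR33, FIP1L1 and PAPOLG. Independent lists would share 279 rising and 1186 falling genes between T4 and T5, 275 and 888 between T4 and CPT, and 346 and 945 between T5 and CPT. The fits share the DMSO library. In 20 simulations with unchanged groups 0 calls were shared. No gene changed in them, so they cannot show how that library affects the overlap of genes that do change. Part of the excess may come from that library.

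Across genes, slopes fitted without DMSO correlated between T4 and T5 with Pearson's r = 0.895 and Spearman's rho = 0.945. For T4 and CPT these were 0.659 and 0.721, and for T5 and CPT 0.682 and 0.736. Genes are not independent replicates, so no p is given. With DMSO in each fit, the covariance of the trends was 0.930, 0.650 and 0.771, against 0.0403, 0.0504 and 0.0540 in simulations with unchanged groups, where the Pearson correlation was 0.363, 0.370 and 0.377. Fitted without DMSO, T4 and T5 shared 1654 rising and 3047 falling genes, T4 and CPT 778 and 1795, and T5 and CPT 1035 and 1804. Independent lists of these sizes would share 447 and 1117, 278 and 769, and 403 and 777, so an excess remained without the shared library.

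T4 against T5 at matched doses. Differences between T4 and T5 were small. FOS was lower with T4 by a mean of 0.92 on the log2 scale (-0.92 ± 0.05), with FPKM values of 61.7 with T4 and 121.9 with T5 at 5 µM. EGR1 (-0.78 ± 0.07), the chemokine CXCL3 (-1.03 ± 0.10), the cytokine IL11 (-1.04 ± 0.17) and NPPC, a natriuretic peptide (-1.09 ± 0.26), were lower with T4 as well. AURKA (0.72 ± 0.12), PLK1 (0.70 ± 0.14) and FRMD6 (0.78 ± 0.06) were higher with T4.

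By limma with Benjamini-Hochberg adjustment, 2807 genes were higher and 641 lower with T4, but only 1 and 5 of them by 1 or more on the log2 scale. For 99.1% of the genes the 95% interval of the difference lay within 1 on either side of 0, with a median distance of 0.122 from the estimate to either end. ATXN7L3B (0.75 ± 0.11) and SCHIP1 (0.68 ± 0.14) were the other named genes higher with T4, and the Wnt receptor FZD8 (-0.92 ± 0.15) the other one lower. Adjusted p of the 10 genes by limma lay between 0.00304 for FOS and 0.0206 for NPPC.

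Of 16 immediate early genes, 11 were lower and none higher with T4 (13 adjusted over the list alone), with NR4A1 at -0.73 ± 0.18 and ATF3 at -0.67 ± 0.07. Camera gave an adjusted p of 3.38e-11, but adjusted p = 0.172 with an estimated correlation. Of 20 G2/M genes, 18 were higher and none lower, also when adjusted over the list alone, with CENPF at 0.59 ± 0.11 and KIF23 at 0.52 ± 0.12. Camera gave 5.08e-05 as adjusted p, but adjusted p = 0.53 with an estimated correlation. Both lists kept their direction with median centring and quantile normalization. Of the cleavage and polyadenylation factors, 5 of 20 were higher with T4 and none lower as deposited (4 adjusted over the list alone), namely WDR33 (0.33 ± 0.06), CSTF2T (0.32 ± 0.06), CPSF4 (0.31 ± 0.06), CPSF7 (0.28 ± 0.07) and CPSF2 (0.18 ± 0.05), but with median centring 3 were higher and 5 lower. PCF11 (-0.0016 ± 0.05), NUDT21 (0.01 ± 0.04), PAPOLA (-0.01 ± 0.03) and CLP1 (0.07 ± 0.05) were not called. Of p53 target genes 6 of 26 were higher and 6 lower (7 and 6 adjusted over the list alone), with CDKN1A at -0.53 ± 0.07, BTG2 at -0.42 ± 0.04, TNFRSF10B at 0.40 ± 0.05 and MDM2 at 0.29 ± 0.08.

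Ribosomal protein genes (3 of 60 lower, 0 adjusted over the list alone), integrated stress response genes (4 of 17 lower, 1 higher, and 1 of each adjusted over the list alone), unfolded protein response genes (6 of 15 lower, 3 higher, and 7 and 3 adjusted over the list alone) and NRF2 target genes (1 of 14 lower, 2 higher, also adjusted over the list alone) were also called lower by camera. Their adjusted p was 3.96e-11, 0.00289, 0.00539 and 0.0495, but adjusted p = 0.53 for each with an estimated correlation, and the ribosomal protein median changed sign with quantile normalization.

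The direction of the split depended on scaling, with 1166 higher and 2622 lower after median centring and 1351 and 1067 after quantile normalization. Without the dose block the test called 0 genes either way, without 2 µM 1647 and 294, without 5 µM 1655 and 298, and without 20 µM 349 lower. The difference of the dose slopes of T4 and T5 gave 0 calls by limma, with 1236 genes at an unadjusted p under 0.05.

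T4 against CPT at matched doses. CDKN1A was lower with T4 than with CPT by a mean of 1.80 (-1.80 ± 0.15), BTG2 by 2.68 (-2.68 ± 0.10), the kinase PLK3 by 2.47 (-2.47 ± 0.16) and the AKT inhibitor PHLDA3 by 2.11 (-2.11 ± 0.10). TOP1 was higher with T4 by 1.03 ± 0.12, with FPKM values of 25.9 with T4 and 14.2 with CPT at 20 µM. EXT1, an enzyme that builds heparan sulphate, was higher by 3.00 ± 0.22, with 59.7 in DMSO, 72.3 with 0.5 µM T4 and 6.88 with 0.5 µM CPT. Among cleavage and polyadenylation factors, CLP1 (-1.98 ± 0.41) and CSTF2T (-1.58 ± 0.14) were lower and FIP1L1 (1.25 ± 0.19) was higher with T4.

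The counts by limma with Benjamini-Hochberg adjustment were 2999 genes higher and 3913 lower with T4. The other named higher genes were KRTAP2-3 (2.64 ± 0.29), the synaptic scaffold GPHN (2.51 ± 0.27), the nuclear pore protein NUP35 (2.43 ± 0.22) and EID3 (2.22 ± 0.34). The lower ones were S1PR3, a receptor of sphingosine 1-phosphate (-3.04 ± 0.16), TMEM177 (-3.03 ± 0.47), FAM220A (-2.85 ± 0.27), FAM46C (-2.81 ± 0.34) and the antiproliferative gene TOB2 (-2.76 ± 0.46). Adjusted p of the 10 genes by limma lay between 0.000385 for S1PR3 and 0.00228 for TOB2.

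Of 26 p53 target genes, 20 were lower and 1, ZMAT3, higher with T4, also when adjusted over the list alone. The camera adjusted p was 0.000203, but adjusted p = 0.621 with an estimated correlation. MDM2 did not pass (0.15 ± 0.23). Of 17 integrated stress response genes, 13 were lower and 2 higher, also when adjusted over the list alone, with CHAC1 at -1.98 ± 0.16, the pseudokinase TRIB3 at -1.60 ± 0.28 and the transcription factor DDIT3 at -1.42 ± 0.16. The camera adjusted p was 0.0346, but adjusted p = 0.621 with an estimated correlation. Of 13 NF-kB target genes 9 were lower and 1 higher, also when adjusted over the list alone, with NFKBIE at -1.91 ± 0.15, RELB at -1.74 ± 0.12 and NFKB1 at 1.66 ± 0.21. That list was not called (adjusted p = 0.0826, camera).

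Higher groups with T4 were 12 of 20 G2/M genes (2 lower, and 13 and 2 adjusted over the list alone), with CENPE at 1.64 ± 0.19 and TPX2 at 1.49 ± 0.10, and 12 of 15 Fanconi anaemia and homologous recombination genes (1 lower, also adjusted over the list alone), with FANCC at 1.13 ± 0.16 and the checkpoint kinase CHEK1 at 0.91 ± 0.13. Their camera adjusted p was 0.000864 and 0.00182, but adjusted p = 0.621 for each with an estimated correlation. Of 20 cleavage and polyadenylation factors 6 were higher and 6 lower, also when adjusted over the list alone. CSTF1 (-1.04 ± 0.23), CPSF4 (-0.52 ± 0.08), CPSF1 (-0.40 ± 0.06) and SYMPK (-0.37 ± 0.09) were lower, and NUDT21 (0.58 ± 0.05), PAPOLA (0.43 ± 0.05), CPSF2 (0.39 ± 0.11), CPSF3 (0.31 ± 0.08) and CPSF6 (0.20 ± 0.06) higher. Among other transcription and splicing genes, INTS5 was lower at -2.59 ± 0.36, as were EXOSC4 at -1.95 ± 0.17, CLK2 at -1.60 ± 0.19 and CDK9 at -1.70 ± 0.19. Of 16 immediate early genes 8 were higher and 4 lower, also when adjusted over the list alone, with EGR1 at 1.60 ± 0.30 and FOSL1 at -2.76 ± 0.36. Of 60 ribosomal protein genes 51 were lower as deposited (52 adjusted over the list alone), with a median of -0.20 that was -0.03 with quantile normalization. Camera gave this list 2.8e-07 as adjusted p, but adjusted p = 0.621 with an estimated correlation.

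Median centring gave 3400 higher and 3008 lower and quantile normalization 3432 and 3137, while without the dose block 1783 were higher and 2328 lower. The dose slopes of T4 and CPT differed for 4797 genes, with the slope of T4 above that of CPT for 1791 and below it for 3006 (limma, common intercept), and for 2745 and 2368 with quantile normalization. With an intercept for each compound 123 were above and 701 below, and of the 4797 calls 600 were kept and 46 reversed, so most calls depend on the common intercept or the DMSO library.

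T5 against CPT at matched doses. CDKN1A was lower with T5 than with CPT by a mean of 1.27 (-1.27 ± 0.20), and BTG2 (-2.26 ± 0.09), PHLDA3 (-2.25 ± 0.08) and the stress proteins SESN2 (-2.19 ± 0.31) and SESN1 (-2.15 ± 0.11) were lower too. FOS and EGR1 were higher with T5 by 2.21 ± 0.29 and 2.38 ± 0.28. TOP1 was higher by 0.85 ± 0.10 and EXT1 by 2.76 ± 0.24. CLP1 (-2.05 ± 0.44), CSTF2T (-1.90 ± 0.17) and CSTF1 (-1.24 ± 0.19) were lower and FIP1L1 (1.19 ± 0.13) higher.

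In this comparison 2645 genes were higher and 3984 lower with T5 (limma, Benjamini-Hochberg). Named higher genes also included KRTAP2-3 (3.39 ± 0.35), EID3 (2.63 ± 0.18) and RPPH1, the RNA of ribonuclease P, which has no poly(A) tail (2.71 ± 0.20). Lower ones were S1PR3 (-3.28 ± 0.14), TMEM177 (-3.18 ± 0.38), FAM220A (-3.05 ± 0.22), FAM46C (-2.86 ± 0.36) and the nuclease EXO5 (-2.77 ± 0.27). Adjusted p of the 10 genes by limma lay between 0.000138 for S1PR3 and 0.000807 for FAM46C.

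Of 26 p53 target genes, 21 were lower and 1, ZMAT3, higher with T5 (21 and 2 adjusted over the list alone), and MDM2 was not called (-0.14 ± 0.17). Camera gave an adjusted p of 0.00207, but adjusted p = 0.896 with an estimated correlation. Of 15 Fanconi anaemia and homologous recombination genes, 9 were higher, with FANCA at 0.87 ± 0.07, and 1, PALB2, was lower (-0.93 ± 0.09), also when adjusted over the list alone. The camera adjusted p was 0.00588, but adjusted p = 0.896 with an estimated correlation. Of 17 integrated stress response genes 12 were lower and 1 higher, of 16 immediate early genes 11 were higher and 4 lower, of 13 NF-kB target genes 3 were higher and 7 lower, and of 20 G2/M genes 7 were higher and 3 lower. These counts were the same adjusted over the list alone, apart from 2 lower for the G2/M list, and camera called none of these lists. Of 20 cleavage and polyadenylation factors 5 were higher and 8 lower as deposited, also when adjusted over the list alone, but 9 and 4 after median centring, with NUDT21 at 0.56 ± 0.05, PAPOLA at 0.44 ± 0.05, CPSF3 at 0.30 ± 0.10, PABPN1 at 0.22 ± 0.07, CPSF4 at -0.83 ± 0.11, CPSF7 at -0.36 ± 0.11, CPSF1 at -0.33 ± 0.06, SYMPK at -0.29 ± 0.09 and WDR33 at -0.25 ± 0.08.

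Median centring gave 3986 higher and 2521 lower, quantile normalization 3623 and 3064, and the test without the dose block 1316 and 2415. The dose slopes of T5 and CPT differed for 3773 genes, with the slope of T5 above that of CPT for 1042 and below it for 2731 (limma, common intercept), and for 2353 and 2147 with quantile normalization. With an intercept for each compound 269 were above and 656 below, and of the 3773 calls 528 were kept and 60 reversed.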

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

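The tests of carry-over and of library scaling were chosen after the result was seen, as were the exchanges within doses and the fit with an intercept for each compound, and the tests of gene span, of other splits and of slope differences were written before it.

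The dose slopes of T4 and CPT differed for 4797 genes and those of T5 and CPT for 3773, by a test of the difference itself (limma), which is what drew attention to both pairs. That fit has a common intercept, so a difference in level counts as slope, and with an intercept for each compound 600 and 528 of these calls were kept and 46 and 60 reversed. Of 100 splits of the 10 treated libraries that ignore dose, 1 of 100 gave as many for each pair (at most 1902 for T4 and 1398 for T5 in another). Dose pairs the libraries, and the 16 exchanges within doses, of which another gave at most 3133 and 2292, are too few for a share under 0.05. Some genes were called in opposite directions with dose. INTS5, a subunit of the Integrator complex, rose with CPT and fell with T4 and T5, and its slopes differed by -4.01 (T4 minus CPT) and -3.94 (T5 minus CPT), or -3.20 and -2.88 with an intercept for each. The co-chaperone BAG3 rose with CPT and fell with both, with differences of -2.74 and -2.70 (-3.65 and -3.38). The co-chaperone DNAJB1 showed differences of -1.21 and -0.96 (-1.95 and -1.53). IRF1, an interferon regulatory factor, rose with CPT and fell with T5, with a difference of -3.42 (-1.51 with an intercept for each, since much of it was in place at 0.5 µM), but its T5 trend was 0.03 with quantile normalization (adjusted p = 0.893, limma).

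Genes with long spans were lower with CPT than with T4. Over 10084 protein-coding genes, the T4 minus CPT difference had a Spearman correlation of 0.617 with gene span, and of genes over 100 kb 71.6% were higher with T4 and 4.03% lower, against 3.77% and 69.9% of genes under 10 kb. With exonic length held fixed the rank correlation was 0.533 (95% bootstrap interval 0.519 to 0.549), and with mean expression held fixed it was 0.641 (0.629 to 0.654), which argues against either as the whole cause. The correlation of span with the dose trend was -0.425 for CPT, -0.116 for T4 and -0.195 for T5, and that with T4 minus T5 was 0.408 (0.281 with exonic length held fixed), a smaller relation that does not involve CPT. Spans came from GRCh38 by gene symbol and genes are not independent, so a difference in how the compounds act on long genes stays a hypothesis, untested by this design.

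ANKRD30BL and LINC00273 rose with every compound, by 5.67 and 5.31 with CPT. A candidate explanation is carry-over of RNA without a poly(A) tail, but only 8 of 24 other such RNAs had enough signal. Their median change lay above that of all genes by 0.463 with CPT (95% interval -0.40 to 1.40), 1.82 with T4 (0.27 to 2.94) and 0.80 with T5 (-0.42 to 2.77). However, 2 of the 8 were 0 in DMSO and in all CPT libraries and hold no value for CPT. Over the 6 above 0 in at least 3 of the 6 libraries of a trend, the same excess was 0.82 (-1.28 to 2.16) with CPT, 1.82 (-0.26 to 2.49) with T4 and 1.77 (0.13 to 3.08) with T5. The intervals and the choice of 6 came after the result was seen, and with so few RNAs carry-over and an effect of the compounds cannot be told apart.

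More genes were higher than lower with T4 against T5 (2807 and 641). After median centring 30.8% of the calls were higher with T4, so the direction of the split depends on the library scaling. Immediate early genes had a lower median and G2/M genes a higher one with T4 as deposited, after median centring and after quantile normalization. Of splits that ignore dose 1 of 100 gave as many calls, with 3448 in the real split and at most 9 in another, but the 16 exchanges within doses (0 calls in any other) are too few for a share under 0.05. Every other split or exchange mixes both compounds within a side, which adds their difference to the scatter, so the low counts decide little. The compounds differed by limma at matched doses, and how they act differently remains an untested hypothesis.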

How the results depend on the processing

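The runs without small RNAs, without 5 and 20 µM T5 and with an intercept for each compound were chosen after the data were seen, and all others before. The labels share no replicate numbers, but the comparisons at matched doses are paired by dose, which is their block, and calls between T4 and T5 depend on it. Counts below are rising and falling, or higher and lower, the cause was not tested except where fewer genes or libraries were tested or a minimum size was asked for, and depth is known only relative to DMSO, so what it limits could not be measured. Median centring and quantile normalization turned the balance of rising and falling genes in all 3 trends, and of higher and lower genes for T4 and T5 against CPT, and median centring also for T4 against T5. Of genes past the threshold in both runs, at most 10 in any trend and 4 in any pair changed sign. Many other calls were no longer past the threshold. With median centring 3542 of 4638 (CPT), 3380 of 4971 (T4), 3921 of 5587 (T5) and 1807 of 3448 (T4 against T5) were kept.

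With median centring the trends gave 3572 and 1643 (CPT), 4293 and 1847 (T4) and 4388 and 1992 (T5), T4 against T5 1166 and 2622, and T5 against CPT 3986 and 2521. Quantile normalization gave 2806 and 2101 (T4), 3013 and 2344 (T5), 1351 and 1067 (T4 against T5), and slope differences of 2745 and 2368 genes (T4 against CPT) and 2353 and 2147 (T5 against CPT), which turns both balances. With an intercept for each compound these were 123 and 701, and 269 and 656. A linear dose scale gave 0 and 0 (CPT), 99 and 1328 (T4) and 23 and 545 (T5). A fit of all 16 libraries gave 3263 rising with CPT, and equal totals without small RNAs 1252, with the balance of T4 against CPT turned (3538 and 3144). With a mean FPKM of at least 5, 1560 rose and 1335 fell with CPT, which turns its balance, 1612 fell with T4 and 1811 with T5, and T4 against T5 gave 1361 and 417, T4 against CPT 1763 and 2297, and T5 against CPT 1630 and 2215. A change of at least 1 left 493 (CPT), 134 (T4) and 281 (T5) rising, and 1 and 5 for T4 against T5, 526 and 879 for T4 against CPT, and 300 and 1006 for T5 against CPT. Without the dose block these pairs gave 0 and 0, 1783 and 2328, and 1316 and 2415. T4 against T5 gave 638 and 115 in a fit of all 15 treated libraries and 397 lower with no filter. Its slope difference gave 19 and 1 with a pseudocount of 0.1. T5 without 5 and 20 µM gave 823 and 2137.

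Leaving out 1 library or dose, CPT ranged from 1 to 2005 rising and 0 to 2920 falling (1 and 0 without 10 µM, 1005 and 1535 without 0.5 µM, 1121 rising without 5 µM). T4 ranged from 785 to 1806 and 2351 to 3494 (785 rising without 0.5 µM, 850 without 10 µM), and T5 from 1152 (without 10 µM) to 2622 and 2618 to 3678. T4 against T5 ranged from 1647 to 2674 and 294 to 756 (1647 and 294 without 2 µM, 1655 and 298 without 5 µM, 349 lower without 20 µM), T4 against CPT from 2586 to 2992 and 3118 to 3828, and T5 against CPT from 2196 to 2606 and 3323 to 4125. Pearson and Spearman correlations of trends with DMSO included were 0.938 and 0.965 (T4 and T5), 0.701 and 0.745 (T4 and CPT) and 0.762 and 0.796 (T5 and CPT), and with quantile normalization 0.891 and 0.946, 0.639 and 0.699, and 0.661 and 0.713.

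Quantile normalization reversed IRF1 in the T5 trend (0.0316) and the ribosomal protein median with T5 (-0.0065) and between T4 and T5 (0.0140). Of named genes, 70 calls were lost and 28 gained with quantile normalization, 39 lost and 28 gained without DMSO, and 3 lost and 2 gained with a pseudocount of 0.1. Of list calls, 27 were lost with an estimated correlation, and 6 were lost and 7 gained with quantile normalization.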

Other observations

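The tests of dose curves, of read-through and of T5 against T4 were chosen after the result was seen, as were the exchanges within doses, and those of other orders and splits were chosen before it. In cholesterol synthesis, SQLE, an enzyme of the pathway, fell by 2.56 ± 0.39 with CPT, 2.56 ± 0.55 with T4 and 2.59 ± 0.47 with T5. SREBF2, which activates the pathway, rose by 0.82 ± 0.11 with T4 and 0.87 ± 0.09 with T5. Of 16 members 4, 4 and 3 rose and 5, 3 and 4 fell with CPT, T4 and T5 (4, 3 and 3 rose and 5, 3 and 4 fell adjusted over the list alone). GCLC, the catalytic subunit for glutathione synthesis, fell by 2.39 ± 0.40, 3.07 ± 0.35 and 3.33 ± 0.28, within NRF2 targets of which 6 of 14 rose with each compound and 2, 5 and 5 fell (7, 6 and 6 rose and 2, 6 and 5 fell adjusted over the list alone). Among hypoxia genes the glucose transporter SLC2A1 fell by 1.17 ± 0.23, 2.60 ± 0.26 and 2.49 ± 0.23, and of 13 members 2, 3 and 2 rose and 3, 4 and 4 fell (3, 3 and 2 rose and 3, 4 and 4 fell adjusted over the list alone). Medians of these lists changed sign with scaling for cholesterol (all compounds), NRF2 (T4 and T5) and hypoxia genes (T4).

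In the unfolded protein response, 7, 7 and 6 of 15 genes rose and 0, 4 and 3 fell with CPT, T4 and T5 (7, 7 and 6, and 0, 5 and 4 adjusted over the list alone). XBP1, its transcription factor, fell by 3.09 ± 0.21 with T4 and 2.64 ± 0.26 with T5, while the chaperone partner CRELD2 rose by 1.26 ± 0.29 with CPT and 1.19 ± 0.22 with T5. With CPT the camera adjusted p was 0.0268, but adjusted p = 0.613 with an estimated correlation, and the same values held for 10 replication-dependent histone genes, of which 4 rose and none fell (5 adjusted over the list alone). With T4 and T5, 2 and 4 of these histone genes rose and 1 fell, also adjusted over the list alone, with HIST1H2AC at -1.05 ± 0.23 and -1.26 ± 0.18. Heat shock genes (14 measured) gave 6, 3 and 5 rising and 4, 4 and 6 falling, and their median changed sign with scaling with every compound. Integrated stress response genes (17) gave 2, 1 and 1 rising and 1, 5 and 4 falling, G1/S and replication genes (20) 1, 3 and 3 rising and 5, 10 and 9 falling, and topoisomerases (6) 0 rising and 3, 3 and 2 falling. The medians of the last 2 lists changed sign with median centring, as did that of integrated stress response genes with T4 and T5. Adjusted over the list alone the counts from heat shock genes onwards were 6, 3 and 6 against 4, 4 and 6, 0, 1 and 1 against 1, 4 and 4, 0, 3 and 3 against 3, 10 and 9, and the same for topoisomerases. With CPT, 4 of 16 SR proteins and CLK kinases fell, 2 of 14 Integrator genes rose and 7 fell (3 and 7 adjusted over the list alone), and 4 of 13 NF-kB targets rose and 1 fell. The osteoblast products COL1A1 and SPARC rose by 0.92 ± 0.12 and 0.81 ± 0.15 with CPT, 0.74 ± 0.12 and 0.73 ± 0.10 with T4 and 0.95 ± 0.16 and 0.84 ± 0.14 with T5, the only 2 of 7 bone genes that rose, and RUNX2 fell with T5 (-0.80 ± 0.26). COL1A1 was abundant, with an FPKM of 300.6 in DMSO. Random lists matched to ribosomal protein genes on expression also lay above DMSO at 20 µM, with medians of 0.53 (CPT), 0.37 (T4) and 0.47 (T5). The rises may thus not be particular to bone genes. Of 5 measured interferon genes 2, 0 and 2 rose and 1, 1 and 2 fell. Epithelial markers (4 of 10 measured) gave 2, 0 and 2 rising, and as KRT18 and KRT8 were abundant in DMSO (FPKM 125 and 88.7) the list is no check for other cells, the blood marker CD68, 1 of 10 measured, was not called, and of 2 aryl hydrocarbon receptor targets 1, 2 and 2 fell. No mitochondrially encoded gene was measured.

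A hypothesis was that T5 moves the same genes further than T4 does. Of 3608 median-centred calls with 1 dose direction in both, 88.7% lay further along it with T5, and 85.2% as deposited, against 67.0% of genes that were not called. A higher potency of T5 would give such a share. The direct test of the dose slopes of T4 and T5 gave 0 calls (limma). Those 0 calls decide little about potency, because the differences were small. At matched doses only 1 called gene was higher and 5 were lower with T4 by 1 or more. In simulated data without curvature the slope test recovered 76% of differences of 1, and smaller ones were not simulated. Median centring turned the balance of the trends and that of T4 against T5 together. An offset between libraries is therefore not excluded by either run. The dose directions and the differences come from the same libraries, so the hypothesis needs other libraries to test it.

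A second hypothesis was that p53 target genes follow a humped curve with T5. The list's median ratio to DMSO with T5 was 0.04, -0.07, -0.11, -0.14 and -0.19 from 0.5 to 20 µM. The list as a whole thus showed no marked hump. On the quadratic dose term camera gave p = 0.0054, but p = 0.0832 with an estimated correlation, and 15 of 26 members had a negative term against 36.0% of all genes. For CPT 25 of 26 were negative (camera p = 0.000112, but p = 0.412 with an estimated correlation) and for T4 16 of 26 (p = 0.0135 and 0.214). A lower quadratic term may thus not be special to T5. Nor was it special to p53 targets. With T5, 13 of the 22 lists tested by camera had a lower term at an adjusted p under 0.05 with the preset correlation (0 with an estimated one). Of these, 9 had a smaller p than p53 targets, among them ribosomal protein, immediate early and heat shock genes. A lower term also comes from a rise that levels off, so it does not show a hump. Immediate early medians with T5 were 0.60, 1.49, 2.05, 2.21 and 2.06 from 0.5 to 20 µM.

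Another hypothesis was that read-through transcripts, named for 2 fused neighbours, rise with T4 and T5. The median of 20 such names exceeded random lists by 0.622 with T4 and 0.641 with T5, which met the bound written for the test, but the excess was 0.742 with CPT. Against their own partner genes, a comparison added after the result was seen, the difference was -0.03 with T4 (95% interval -0.27 to 0.22) and 0.0039 with T5 (-0.23 to 0.45), and with CPT 0.31 (0.02 to 0.69). With T4 3 names rose and 3 fell, and with T5 2 and 2. The data leave open whether read-through changed, since FPKM of fused names may hold fragments of the partner genes.

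Other orders of the 6 libraries of each trend were fitted, 100 with the real one. For T5 the real order gave 5587 calls, against at most 2001 in another order drawn. That sets the real order apart from those drawn, but not all orders were drawn, so chance is not excluded. For CPT (4638) and T4 (4971) 1 of 100 orders, the real one, gave as many, a share under 0.05. Another order reached 4595 (CPT) and 4960 (T4), and not all orders were drawn. The count therefore hardly separates the real order from others, and chance is not excluded for these trends. Of splits of 10 treated libraries that ignore dose, 1 of 100 gave as many calls for T4 against CPT (6912, at most 10 in another) and for T5 against CPT (6629, at most 12), but the 16 exchanges within doses (0 calls in any other) are too few for a share under 0.05. Here too every other split or exchange mixes both compounds within a side, so the low counts decide little. For the slope difference of T4 and T5 the count decides nothing, since with 0 calls by limma (1236 genes at an unadjusted p under 0.05) all 100 of 100 splits must give as many. Another split gave 1532. These splits ignore dose, so their sides can hold different doses, whereas the 16 arrangements that exchange compounds within doses all gave 0 calls. The source of the 1532 calls was not tested.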
